A study of Mus musculus with 18 samples.

How the data were processed

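RNA was measured in 18 samples of bone marrow-derived macrophages from male FVB/NJ mice, wild type (WT) or knockout (KO) for Klf3, a zinc finger transcription factor of the Krüppel-like family. Marrow cells were grown for 7 to 10 days in medium conditioned by L929 cells, a source of the growth factor M-CSF. That medium was then replaced with regular medium, and cells were harvested at once (0 h) or after 8 h with lipopolysaccharide (LPS, 100 ng/mL) or its vehicle, phosphate-buffered saline. Each of the 6 groups holds 3 samples, and each sample was hybridised to 1 array of an Affymetrix GeneChip HT MG-430PM plate after labelling with a 3' IVT kit.

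The deposited values are intensity on a linear scale, 1 value per probe set and array, made with Partek per the submitters' processing notes. The version of Partek, the background correction and any scaling are not given in the sources used here. The quantiles of the 18 columns differed (the median ran from 11.4 to 18.6), so the values had not been brought to a common distribution. The planned analysis had assumed log2 values that were already normalized between arrays. Because they were neither, the log2 was taken and the arrays were quantile-normalized before every test. This departure was chosen after seeing the data.

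Of 45141 probe sets, 104 control probe sets were left out. Among the remaining 45037, 28898 were assigned to exactly 1 gene symbol, 551 to several genes and 15588 to no listed gene. The probe set with the highest mean over the 18 arrays stood for each gene, which gave 17097 genes, 7180 of them with more than 1 probe set. No filter on dim probe sets was applied. No genome build is named for the array, so positions are not printed, and GRCm38 gene positions for 16937 genes were used only to find the neighbours of Klf3. For arrays, the number per group limits the precision, and no depth applies. As a level for absent signal, the 95th percentile of 23 nonspecific control probe sets was taken in each array, a choice made after seeing the data. Where every array of the dimmer group lay at or under that level, the fold differences of the genes with the largest changes are given as "at least", computed against the level. Log2 differences are as fitted, also where a group lies under the level, unless the text says that values were raised to it.

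The groups, the 10 comparisons, the test, the gene lists and the rule for naming genes were fixed before the data were examined. A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, followed by its empirical Bayes moderated test. P-values are two-sided and Benjamini-Hochberg adjusted over the genes tested within a comparison, with a threshold of 0.05, and errors of log2 differences are standard errors from this fit. The comparisons were LPS against vehicle in each genotype and the difference between those responses (an interaction contrast), KO against WT at 0 h, after vehicle and after LPS, vehicle against 0 h in each genotype and the difference between those, and KO against WT over the 3 conditions. For the last of these the 3 arrays of a genotype with the same replicate number, 1 from each condition, were averaged first, which left 3 averages per genotype. These numbers are not known to mark shared cultures, so an average is a set of arrays and not an established culture. Leaving out a replicate, such as KO replicate 1, leaves out all 3 arrays with that number. The labels do not say whether replicates come from separate animals or cultures, so the p-values measure only the spread between these samples.

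A total of 37 gene lists was fixed in advance, with 605 of 688 entries matched to a gene on the array. These were pro-inflammatory cytokines, chemokines, interferon-stimulated genes, guanylate-binding proteins and IRG GTPases, NF-kB subunits and inhibitors, LPS receptor and TLR signalling, feedback inhibitors of inflammation, alternative activation markers, and nitric oxide, itaconate and superoxide enzymes. Metabolic and stress lists were glycolysis and HIF1 targets, mitochondrial respiratory chain, cholesterol synthesis and SREBP2 targets, LXR targets and cholesterol efflux, lysosomal hydrolases and membrane proteins, endoplasmic reticulum stress, and NRF2 targets. Further lists were MHC class II and co-stimulation, MHC class I and antigen processing, macrophage identity, proliferation, immediate early genes, KLF and SP family, KLF3 targets, KLF3 cofactors, and galectins. Cell type lists were neutrophil, monocyte, dendritic cell, osteoclast, T and NK cell, B cell and plasma cell, erythroid and megakaryocyte, mast cell and basophil, eosinophil, stromal and fibroblast, endothelial and adipocyte, and stem and progenitor cell markers. Lists were tested with camera from limma at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Counts of members past the threshold are given over all genes and adjusted over the list alone, and where 1 count is given for a called list, both were equal. The KLF3 targets list, with 3 measured members, was below the minimum of 5 and was not tested as a list.

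Genes are named by a rule. In a comparison with calls, these are the 10 largest rises and the 10 largest falls among genes past the threshold whose 2 groups of arrays did not overlap. Chance alone keeps 2 groups of 3 arrays apart for 10% of genes. For the interaction and the average, passing the threshold was enough. Symbols of predicted genes were counted but not named. Klf3 and the KLF3 targets are always given, as are up to 4 members with the largest change in each list described, and the 4 genes with the smallest p in a comparison without calls. A gene named in one comparison may be given in others.

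Alternatives planned in advance were shifting arrays to the same median, leaving out dim genes, averaging probe sets per gene, testing every probe set, eBayes with trend and robust settings, fitting only the groups compared, blocking by plate column, replicate number within or across genotypes, leaving out genes near Klf3, and leaving out each replicate number of a genotype in turn. Alternatives chosen after seeing the data were the deposited values without normalization, a shift to the same hybridisation controls (9 probe sets), leaving out single arrays, raising values to the nonspecific level, and a separate spread for each group (limma array weights shared within the group). The procedure was tested on simulated data with 200 changed genes among 17097. Of log2 changes of 1, the 7 comparisons of 2 groups recovered between 70% and 81%. The LPS interaction recovered 44% of changes of 1 and 94% of changes of 2. The vehicle interaction had the lowest recovery, 36% and 84%. Unchanged genes made up 2.1% to 8.1% of calls, most for LPS in KO cells. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.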

Results

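The series compares WT and Klf3 KO bone marrow-derived macrophages before and after 8 h of LPS, a Gram-negative outer membrane component sensed by TLR4. The 6 groups of 3 arrays were WT and KO cells at 0 h and after 8 h of vehicle or LPS. The upper quartile of intensity was 144 ± 22 in WT and 130 ± 14 in KO cells at 0 h (mean ± SD, n = 3 arrays). It was 119 ± 9 and 106 ± 8.9 after vehicle, and 71 ± 4.6 and 89.9 ± 16 after LPS. Between 52.5% and 58.7% of genes lay above the nonspecific control level in each array. The first principal component held 62.8% of the variance and separated the LPS arrays from all others, and the second held 11.8%. Each plate row held 1 condition, so row and treatment cannot be told apart. Each of the 3 plate columns held 1 WT and 1 KO array per condition. These lay in different rows, KO in the upper one only in column 7, so a column block leaves row and genotype mixed.

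The RNA quality measure on the array moved with treatment. The signal of the 5' Gapdh control minus that of the 3' control, in log2, was 0.117 ± 0.015 in WT and 0.0933 ± 0.074 in KO cells at 0 h (SD, n = 3). It was -0.18 ± 0.096 and -0.217 ± 0.093 after vehicle, and -0.44 ± 0.34 and -0.47 ± 0.085 after LPS. The spread was widest in the WT LPS group. The standard deviation from the group mean over all genes (log2) was 0.336, 0.277 and 0.296 in its 3 arrays and between 0.165 and 0.266 elsewhere, highest in KO vehicle array 3. On the third principal component WT LPS array 3 lay at -15.3 and the other 2 at -30.75 and -33.08.

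Klf3 itself was read by 6 probe sets, and the labels do not say which of them lie in the deleted part of the gene. A probe set outside that part need not change with the genotype. Probe set 1421604_PM_a_at fell from 295 ± 19.6 to 14.6 ± 5.1 intensity units at 0 h (mean ± SD, n = 3 arrays each), from 222 ± 63.1 to 12.2 ± 6.55 after vehicle and from 138 ± 87.4 to 8.2 ± 2.22 after LPS. The KO signal of this probe set was 16.9-fold lower at 0 h as fitted (12.5-fold with values raised to the nonspecific level), at least 13.2-fold lower after vehicle and at least 10.5-fold lower after LPS (adjusted p = 0.000398, 0.000489 and 8.87e-06 over every probe set). It lay just above that level in 2 of 3 KO arrays at 0 h and above it in no KO array after vehicle or LPS. Probe set 1429360_PM_at was 3.62-fold, 4.64-fold and 7.33-fold lower, with 181 to 362 units in the WT arrays and 28.2 to 68.1 in the KO arrays. The probe set that stood for Klf3 among the tested genes, 1454666_PM_at, was 2.27-fold, 3.78-fold and 4.86-fold lower, with no overlap between the 9 WT arrays (293 to 657) and the 9 KO arrays (62.8 to 222). At the gene level its adjusted p was 0.185 at 0 h, 0.053 after vehicle and 0.000188 after LPS. Another, 1431630_PM_a_at, read 1.51, 1.31 and 0.24 (log2) higher in KO cells (adjusted p = 0.133, 0.502 and 0.787). WT replicate 2 read 508 units at 0 h and 261 after vehicle, other WT arrays at most 171. Neither 1441200_PM_at nor 1442920_PM_at passed.

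**Figure D1:**
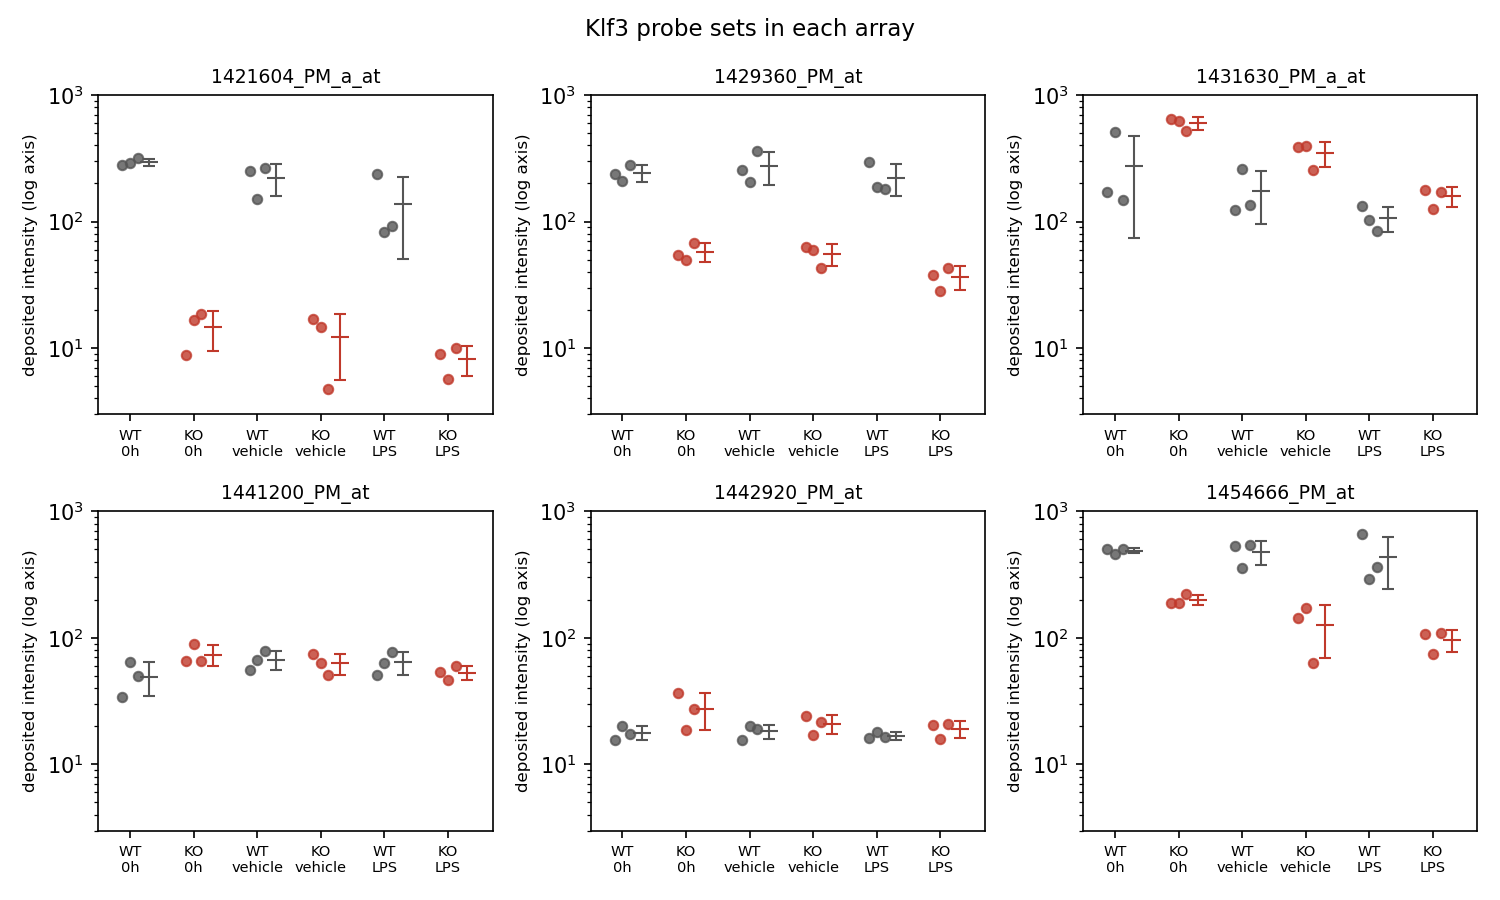
Deposited intensity (log axis) of the 6 Klf3 probe sets in each array of the 6 groups; points are arrays and bars are the mean ± SD of 3 arrays. For 1421604_PM_a_at the 9 KO arrays lie between 4.76 and 18.5 and the 9 WT arrays between 82.9 and 317, while 1431630_PM_a_at shows no lower signal in KO cells.

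LPS against vehicle in WT cells gives the response of normal macrophages to LPS. The largest rise was in Lcn2, which encodes the iron-withholding protein lipocalin, by 9.92 ± 0.25 (log2 ± SE, n = 3 arrays each), at least 319-fold (adjusted p = 2.51e-13). The chemokine genes Cxcl11 (7.74 ± 0.38, at least 115-fold) and Ccl5 (7.34 ± 0.29) rose. The cytokine genes Il1a (7.30 ± 0.36, at least 61.7-fold), Il6 (7.20 ± 0.38, at least 47.8-fold) and Il1b (6.97 ± 0.37) rose as well. So did the complement gene Cfb (7.25 ± 0.20, at least 94.1-fold), Ptgs2, the inducible cyclooxygenase (6.97 ± 0.48), the metalloprotease gene Mmp14 (7.06 ± 0.16) and the co-stimulatory receptor gene Cd40 (6.88 ± 0.37). The largest falls were in the sialyltransferase gene St6gal1 (-6.43 ± 0.36, at least 30.3-fold lower), Tmem154 (-6.32 ± 0.35, at least 20.8-fold), Arhgap19 (-6.01 ± 0.52), and Nav2 (-5.68 ± 0.35, at least 22.3-fold). Next came Rnf144b (-5.62 ± 0.28), the mTOR inhibitor gene Deptor (-5.44 ± 0.24, at least 11.6-fold) and the receptor gene Gpr34 (-5.35 ± 0.48, at least 11-fold). They were followed by Abcd2 (-5.09 ± 0.36, at least 11.7-fold), Rnf150 (-4.98 ± 0.37) and the cannabinoid receptor gene Cnr2 (-4.92 ± 0.39). In all, 5522 of 17097 genes passed the threshold, 2347 higher and 3175 lower, of which 899 and 1270 changed at least 2-fold.

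Inflammatory lists rose in WT cells after LPS. Among 19 pro-inflammatory cytokine genes 14 rose, 0 fell and 5 were not past the threshold, with 14 and 0 when adjusted over the list alone, a median log2 change of 2.72, and 2.47 with values raised to the nonspecific level. Il12b, encoding a subunit shared by a pair of T cell-polarizing cytokines, rose by 6.26. Of 21 chemokine genes 18 rose and 3 were not past the threshold (18 higher and 1 lower adjusted over the list alone; median 2.85, 2.22 with that floor), among them Ccl7 (5.94), Cxcl10 (5.68) and Cxcl1 (5.27). All 35 interferon-stimulated genes rose (median 2.69), with Oasl1 at 6.09, Mx1 at 5.59, Isg20 at 5.40 and Ifit1 at 4.98. Of 10 guanylate-binding proteins and IRG GTPases, cell-autonomous defence factors, 9 rose (10 adjusted over the list alone; median 4.02), including Gbp3 (6.31) and Gbp2 (5.12). Among 19 NF-kB subunits and inhibitors 17 rose and 2 fell, with the same counts over the list alone, and Traf1 (6.57), Nfkbie (3.08), Nfkb2 (2.97) and Tnfaip3 (2.75) rose (median 1.53). Feedback inhibitors of inflammation (20 measured, 14 higher, 2 lower, median 1.96) included Socs3 (6.80), Ptges (6.40) and Il1rn (5.81). Of 10 nitric oxide, itaconate and superoxide enzymes 8 rose (median 2.56), with the arginine-supplying Ass1 at 4.40, Acod1, which makes itaconate, at 4.25, Nos2 at 3.77 and Gch1 at 3.02. Adjusted p by camera for these 7 lists ran from 5.74e-32 for the interferon-stimulated genes to 4.62e-07 for the nitric oxide list. With an estimated correlation it was 0.0185, 0.00778, 0.0446, 0.04, 0.00609, 0.00778 and 0.0115 in the order given.

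Metabolic and housekeeping lists also moved with LPS in WT cells. Of 22 glycolysis and HIF1 targets 18 rose and 1 fell (19 and 2 over the list alone; median 0.85, adjusted p = 1.16e-09, and 0.0593 with an estimated correlation). Among its members were Pfkfb3 (3.55), the lactate transporter gene Slc16a3 (3.47) and the glucose transporter gene Slc2a1 (2.80). Of 19 cholesterol synthesis genes and SREBP2 targets 14 fell and 0 rose (median -1.10, adjusted p = 1.71e-05, and 0.228 with an estimated correlation). Examples were Cyp51 (-2.32 ± 0.48), Dhcr7 (-2.11), Msmo1 (-1.94) and Idi1 (-1.83). Of 34 proliferation genes 21 fell, 0 rose and 13 were not past the threshold (0 and 22 over the list alone; median -1.64, adjusted p = 2.38e-08, and 0.272 with an estimated correlation). Among 24 lysosomal hydrolases and membrane proteins 19 fell and 1 rose (median -0.57, adjusted p = 1.24e-07, and 0.04 with an estimated correlation). Of 34 mitochondrial respiratory chain genes 13 fell, including Sdha (-0.70), and 1, Cycs (1.43), rose (median -0.21, adjusted p = 0.00844, and 0.161 with an estimated correlation). This call ended under the other scalings, with adjusted p from 0.00751 to 0.633 over the alternatives. MHC class I and antigen processing (15 measured, 10 higher, 1 lower, median 0.79, adjusted p = 6.43e-06, and 0.125 with an estimated correlation) included the proteasome genes Psmb10 (1.71) and Psme2 (1.66). Of 18 NRF2 targets 9 rose and 3 fell (9 and 4 over the list alone; median 0.44, adjusted p = 0.0135, and 0.5 with an estimated correlation). Of 27 LPS receptor and TLR signalling genes 14 rose and 5 fell, with Irak3 at 3.04, Tlr1 at 2.83 and Tlr8 at -1.45 (adjusted p = 0.00257, and 0.161 with an estimated correlation). Its median was 0.40, but -0.29 with deposited values and -0.28 when arrays were shifted to the same hybridisation controls. MHC class II and co-stimulation (14 measured, 5 higher, 1 lower, adjusted p = 0.0376, and 0.4 with an estimated correlation) had a median of 0.38, but -0.09 and -0.07 under those scalings. Its call ended without WT replicate 1 (adjusted p 0.00603 to 0.4 over the alternatives).

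The scaling of the arrays set the balance of directions in WT cells. Higher and lower genes numbered 1581 and 3866 when arrays were shifted to the same median, 743 and 6702 with deposited values, and 631 and 4881 with equal hybridisation controls. The median change over all genes was -0.054, -0.442 and -0.428 (log2) under the same 3 scalings, against -0.007 after quantile normalization, so a change smaller than about this shift has no settled direction.

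The response of KO cells to LPS held many of the same genes. In KO cells Il6 rose by 9.89 ± 0.38 (log2 ± SE, n = 3 arrays each), at least 381-fold (adjusted p = 1.11e-11), Ptgs2 by 9.09 ± 0.48, Il1a by 9.03 ± 0.36 (at least 237-fold), and Lcn2 by 8.83 ± 0.25 (at least 173-fold). Cd40 rose by 8.11 ± 0.37, Il12b by 7.90 ± 0.32 (at least 135-fold), Il1b by 7.73 ± 0.37, Shisa3 by 7.70 ± 0.33 (at least 88.2-fold) and Ccl5 by 7.54 ± 0.29. The scavenger receptor gene Marco rose by 7.40 ± 0.29 (at least 97.5-fold). The largest falls were in Arhgap19 (-6.37 ± 0.52, at least 26.2-fold), St6gal1 (-5.87 ± 0.36, at least 24.5-fold), Zdhhc14 (-5.79 ± 0.35), Tmem154 (-5.65 ± 0.35, at least 20.7-fold), and Cnr2 (-5.60 ± 0.39, at least 11.9-fold). Nav2 (-5.57 ± 0.35, at least 18.2-fold) came next, then Cenpf (-5.54 ± 0.52), Rgs2 (-5.38 ± 0.24), the cell cycle inhibitor gene Cdkn2c (-5.17 ± 0.64) and Pde3b (-5.11 ± 0.37). In all, 5894 genes passed, 2374 higher and 3520 lower, with 972 and 1447 at least 2-fold. Of the genes that rose, 1669 did so in both genotypes, where 326 were expected for independent lists, and 2562 fell in both against 654 expected. Across all 17097 genes, which are not independent replicates, the log2 changes of the genotypes correlated with r = 0.885. Shifting arrays to the same median gave 2755 higher and 2974 lower genes, deposited values 1646 and 3099, and equal hybridisation controls 1211 and 2231, with a median change over all genes of 0.093, -0.026 and 0.004.

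In KO cells after LPS, 18 of 19 pro-inflammatory cytokine genes rose and 0 fell (median 4.38, 3.89 with values raised to the nonspecific level, adjusted p = 1.03e-21). Of 21 chemokine genes 18 rose and 1 fell (median 4.55, and 3.94 with that floor, adjusted p = 4.94e-16). All 35 interferon-stimulated genes (median 2.88) and all 10 guanylate-binding proteins and IRG GTPases (median 3.97) rose, as did 17 of 19 NF-kB subunits and inhibitors, with 1 lower (median 1.71). Feedback inhibitors (12 higher and 3 lower of 20, 12 and 4 over the list alone, median 2.84), nitric oxide, itaconate and superoxide enzymes (8 of 10 higher, median 2.84) and lysosomal genes (21 lower and 1 higher of 24, median -0.76) were called too. With an estimated correlation these 8 calls held, at adjusted p = 0.0027, 0.0034, 0.0472, 0.0393, 0.0027, 0.00885, 0.0095 and 0.0274. Of 34 proliferation genes 23 fell (25 over the list alone; median -2.01, adjusted p = 1.75e-10, and 0.225 with an estimated correlation). Glycolysis and HIF1 targets (16 higher and 2 lower, 17 and 2 over the list alone, median 0.90, adjusted p = 2.72e-07), LPS receptor and TLR signalling (13 higher and 5 lower, 14 and 5 over the list alone, median 0.39, adjusted p = 0.000549) and MHC class I and antigen processing (11 higher, 1 lower, median 0.82, adjusted p = 4.12e-06) each had adjusted p = 0.116 with an estimated correlation. MHC class II and co-stimulation (7 higher of 14, median 0.95, adjusted p = 0.000406, and 0.167 with an estimated correlation) included the co-stimulatory ligand gene Icosl (2.76). Endoplasmic reticulum stress (9 higher of 19, 10 higher and 1 lower over the list alone, median 0.44, adjusted p = 0.000694) and NRF2 targets (11 higher and 1 lower of 18, 12 and 2 over the list alone, median 0.75, adjusted p = 4.66e-05) each had adjusted p = 0.252 with an estimated correlation. Of 13 LXR targets and cholesterol efflux genes 8 fell and 2 rose (median -1.62, -0.81 with that floor, adjusted p = 0.00925, and 0.302 with an estimated correlation). Examples were Apoc2 at -4.92 and the sterol hydroxylase gene Cyp27a1 at -4.65. The respiratory chain list (12 lower, 1 higher, median -0.25, adjusted p = 0.00925, and 0.148 with an estimated correlation) had a median of 0.11 with equal medians and 0.02 with equal hybridisation controls. This call ended without KO replicate 3 (adjusted p over the alternatives 0.00684 to 0.74). Of the 19 cholesterol synthesis genes 3 rose and 2 fell in KO cells (median 0.33, adjusted p = 0.359).

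The interaction contrast tests whether the LPS response differs between genotypes. The gene with the largest difference was Csf2, which encodes the growth factor GM-CSF. It lay under the nonspecific control level in every WT array and in every KO array without LPS. It rose in KO cells by 6.47 ± 0.19 (log2 ± SE), to a log2 intensity of 9.24 ± 0.43 (SD, n = 3 arrays), against 3.07 ± 0.31 in WT cells after LPS. Its difference in response was 6.26 ± 0.27 (adjusted p = 1.75e-09). Larger responses in KO cells were also found for the cytokine genes Il23a (3.82 ± 0.46, adjusted p = 0.000466), Lif (3.76 ± 0.28, adjusted p = 4.25e-06), Il12a (3.68 ± 0.39, adjusted p = 0.000153) and Inhba (3.72 ± 0.55, adjusted p = 0.00231). The orphan nuclear receptor gene Nr4a3 (3.65 ± 0.47), the aggrecanase gene Adamts4 (3.62 ± 0.35), Lad1 (3.20 ± 0.31), the sterol demethylase gene Cyp51 (3.16 ± 0.68) and the transcription factor gene Egr2 (3.13 ± 0.63) completed the 10 largest. Like Csf2, the genes Il23a, Lif, Nr4a3 and Adamts4 lay under the nonspecific level in every WT array after vehicle or LPS, so their fitted values rest in part on background and their order is not settled. With values raised to that level the differences were 5.10 for Csf2, 3.33 for Inhba, 3.05 for Adamts4, 3.01 for Egr2, 3.00 for Cyp51, 2.94 for Lad1, 2.83 for Il12a, 2.71 for Lif, 2.59 for Nr4a3 and 2.09 for Il23a. The acute phase gene Saa1 rose by 4.39 ± 0.43 in WT cells and stayed at or under the nonspecific level in KO cells, a difference of -4.56 ± 0.61 (adjusted p = 0.00112). Hp, which encodes the hemoglobin-binding protein haptoglobin, rose by 6.43 ± 0.23 in WT and 3.64 ± 0.23 in KO cells, a difference of -2.79 ± 0.33 (adjusted p = 0.00042). Lower values of the interaction were further found for Gins1 (-2.78 ± 0.40), Cacna1d (-2.73 ± 0.46), Ly6i (-2.70 ± 0.40), the protease inhibitor gene Timp1 (-2.59 ± 0.60), Zc3h12d (-2.58 ± 0.34), Zfp618 (-2.38 ± 0.43), Zdhhc14 (-2.33 ± 0.49) and Adssl1 (-2.33 ± 0.45). With that floor Saa1 was at -2.71, Gins1 at -1.92 and Adssl1 at -1.17.

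In all, 191 genes had a different LPS response, 89 with a higher and 102 with a lower value in KO cells, and 75 and 77 of them differed at least 2-fold. Of the 89, 39 rose and 22 fell in WT cells, and 71 rose and 6 fell in KO cells. Of the 102, 50 rose and 24 fell in WT cells, and 14 rose and 62 fell in KO cells. The split of directions followed the scaling, with 144 higher and 42 lower when arrays were shifted to the same median, 278 and 16 with deposited values, and 112 and 10 with equal hybridisation controls. The median of all genes was 0.171, 0.44 and 0.456 under these scalings. Of the 89 higher genes 86, 89 and 68 stayed called, and of the 102 lower ones 40, 16 and 9. With only the arrays of these 4 groups in the fit 80 genes were called, and 161 with a separate spread for each group. The count was 114, 70 or 94 without KO replicate 1, 2 or 3 and 71 without WT replicate 2. Without single LPS arrays it was 499 (WT array 1), 373 (WT array 3) and 123 (KO array 3). The calls for Cyp51, Egr2, Timp1, Zfp618, Zdhhc14 and Adssl1 ended in some alternatives, with an adjusted p of up to 0.246, 0.143, 0.227, 0.0971, 0.198 and 0.11. For Cyp51 this was so without KO replicate 1, 2 or 3 or WT replicate 1, with values between 2.35 and 3.69 over all alternatives.

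Of 19 pro-inflammatory cytokine genes 9 had a higher LPS response in KO cells and 0 a lower one (12 and 0 adjusted over the list alone; median 1.64, adjusted p = 2.62e-20, and 0.00682 with an estimated correlation). Besides those named above they included Il6 (2.69 ± 0.53, adjusted p = 0.0182) and Tnf (2.29 ± 0.45, adjusted p = 0.0169), while Il12b was at 1.64 (adjusted p = 0.121) and Il1a at 1.73 (adjusted p = 0.135). Of 21 chemokine genes 5 were higher and 0 lower (6 and 1 over the list alone; median 0.93, adjusted p = 4.74e-06, and 0.13 with an estimated correlation). Members included the dendritic cell and T cell attractants Ccl22 (3.13 ± 0.28) and Ccl17 (2.12 ± 0.23), the neutrophil attractant Cxcl5 (2.52 ± 0.39) and Cx3cl1 (2.18 ± 0.29). Of 19 cholesterol synthesis genes 6 were higher (13 over the list alone; median 1.29, adjusted p = 1.31e-14, and 0.13 with an estimated correlation). They included Idi1 at 2.47 ± 0.46 and Insig1 at 2.28 ± 0.43 beside Cyp51. Cyp51 fell by 2.32 after LPS in WT cells, and its change in KO cells was 0.85 (adjusted p = 0.205). Of 20 immediate early genes 3 were higher (5 higher and 2 lower over the list alone; median 0.41, adjusted p = 0.00176, and 0.364 with an estimated correlation). Endoplasmic reticulum stress (0 past the threshold, 3 higher over the list alone, median 0.43, adjusted p = 4.47e-06, and 0.286 with an estimated correlation) was called upward. So were MHC class II (1 higher, Icosl at 0.69, 2 over the list alone, median 0.51, adjusted p = 0.000442, and 0.359 with an estimated correlation) and NRF2 targets (1 higher, Slc7a11 at 1.99 ± 0.37, median 0.22, adjusted p = 0.000298, and 0.5 with an estimated correlation). The NRF2 call ended without KO replicate 2 (adjusted p over the alternatives 1.1e-08 to 0.5). Among 7 monocyte markers, 1, Hp, was lower (2 over the list alone; median -1.13, adjusted p = 0.00225, and 0.213 with an estimated correlation). The proliferation list had 0 members past the threshold (1 lower over the list alone), with adjusted p = 0.029, and 0.833 with an estimated correlation. Its median was -0.28 but 0.20 with deposited values and 0.21 with equal hybridisation controls, and the call ended without KO replicate 3 or WT replicate 1 (adjusted p over the alternatives 0.000244 to 0.833). Among lists without a call here, the interferon-stimulated genes had a median difference of 0.06 (adjusted p = 0.436), and guanylate-binding proteins and IRG GTPases 0.22 (adjusted p = 0.764). The median was 0.04 for LPS receptor and TLR signalling (adjusted p = 0.406), 0.11 for NF-kB subunits and inhibitors (adjusted p = 0.25) and 0.13 for feedback inhibitors (adjusted p = 0.494). Over the list alone 2 members were higher and 2 lower in the last 2 of these lists each. Single members of the latter lists passed, among them the cytokine signal inhibitor gene Cish (2.80 ± 0.24), Nfkbiz (1.39) and Bcl6 (-1.70 ± 0.27), and Pfkfb3 of the glycolysis list was at -1.32 ± 0.25.

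**Figure D2:**
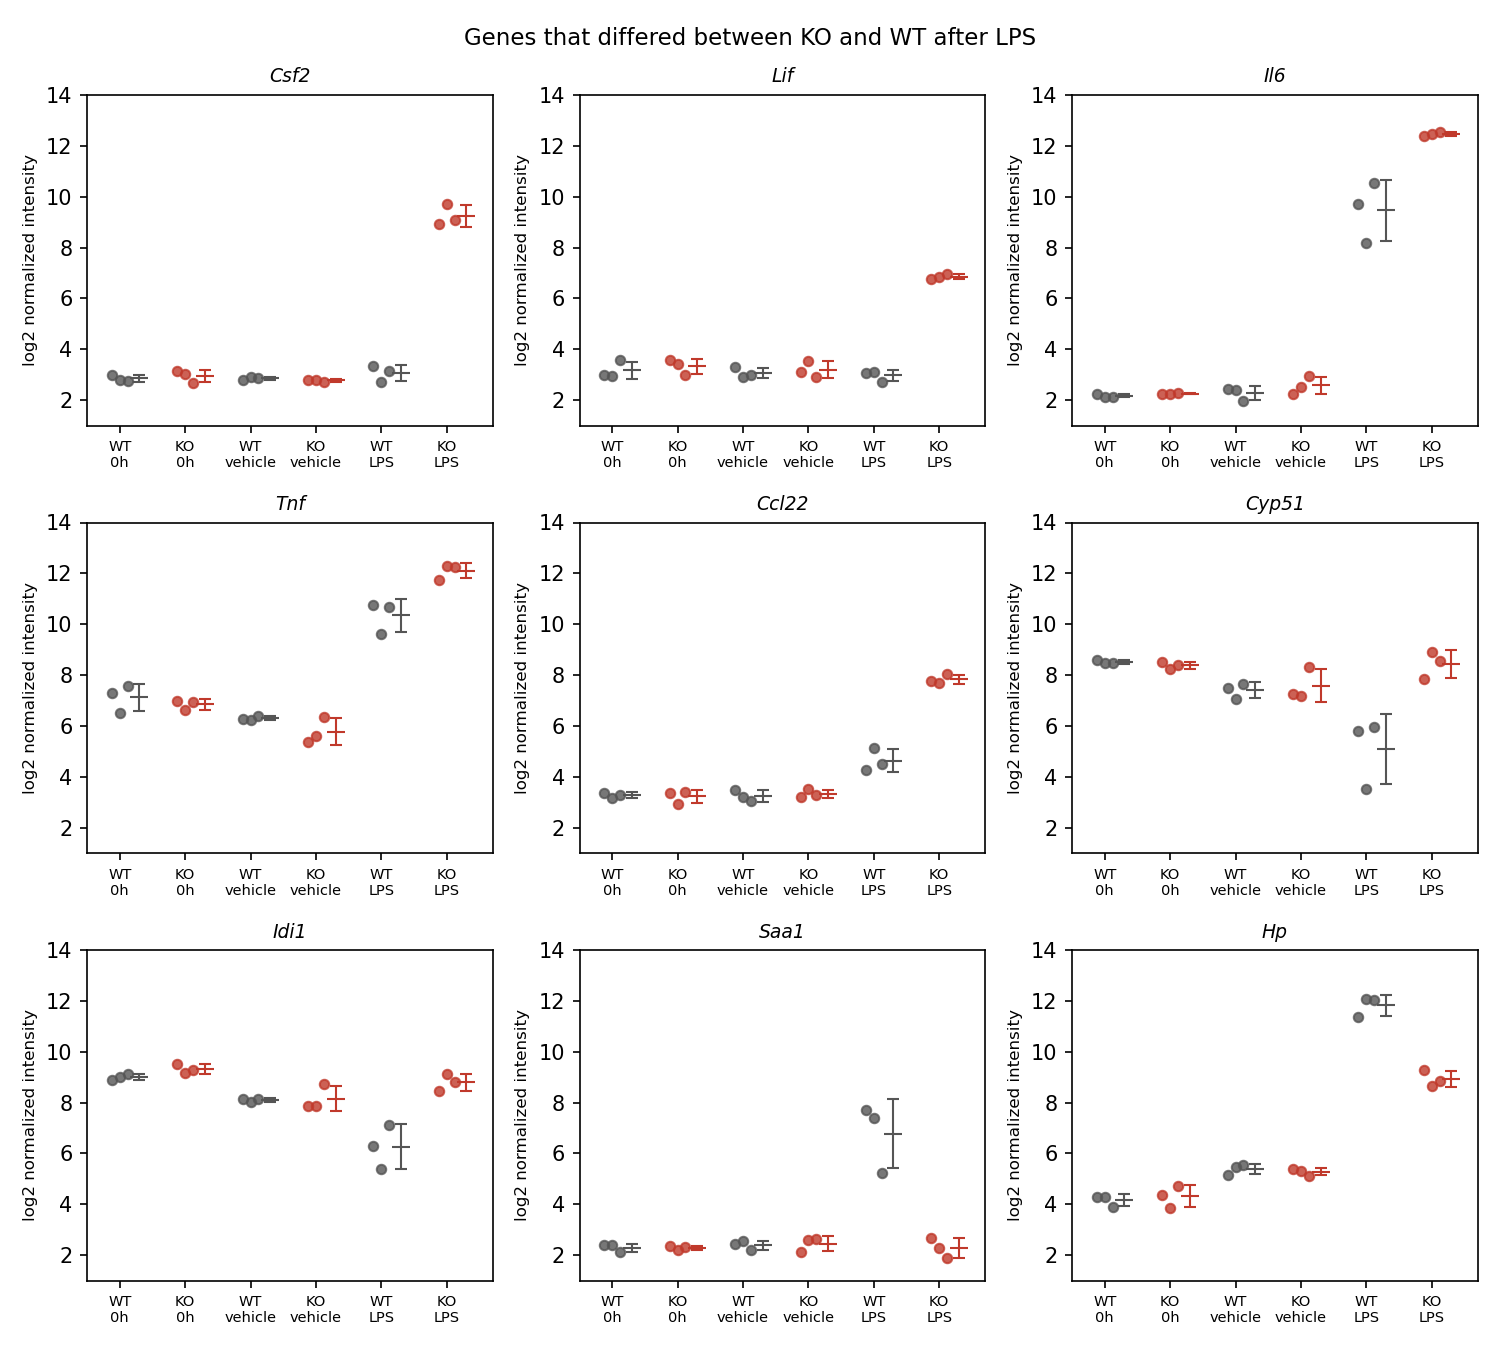
Log2 normalized intensity of Csf2, Lif, Il6, Tnf, Ccl22, Cyp51, Idi1, Saa1 and Hp in each array of the 6 groups; points are arrays and bars are the mean ± SD of 3 arrays. After LPS the KO and WT means are 9.24 and 3.07 for Csf2, 12.47 and 9.47 for Il6, and 2.29 and 6.78 for Saa1.

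KO against WT after LPS compares stimulated cells. KO cells held at least 34.3-fold more Csf2 RNA (6.18 ± 0.19 log2, adjusted p = 9.55e-12), and at least 6.54-fold more Lif (3.88 ± 0.20), with 3 arrays in each group. They held at least 6.05-fold more Nr4a3 (3.84 ± 0.33), at least 8.3-fold more Adamts4 (3.82 ± 0.25) and at least 4.26-fold more Il23a (3.63 ± 0.32). Higher as well were Il12a (3.81 ± 0.28), Inhba (3.34 ± 0.39), Cyp51 (3.34 ± 0.48, 10.1-fold), the inhibitory receptor gene Havcr2 (3.26 ± 0.48) and Ccl22 (3.21 ± 0.20, 9.23-fold). Lower in KO cells were Saa1 (-4.49 ± 0.43, at least 6.52-fold) and Saa2 (-2.70 ± 0.52, at least 3.48-fold), Hp (-2.90 ± 0.23, 7.47-fold), and Ifitm6 (-3.49 ± 0.73). So were the calcium channel gene Cacna1d (-3.10 ± 0.32), the lectin gene Clec10a (-3.07 ± 0.58), the complement gene C1qb (-3.04 ± 0.49), Timp1 (-2.94 ± 0.42), Arg1, the arginase of alternatively activated macrophages (-2.85 ± 0.63), and Pltp (-2.60 ± 0.45). In all, 1019 genes differed, 480 higher and 539 lower, with 185 and 171 at least 2-fold. Within the 3 plate columns Csf2 differed by 6.40, 5.75 and 6.38 and Saa1 by -5.43, -2.54 and -5.50. Of the 1019 genes 1003 kept 1 sign in all 3, which is likely for genes called on the same arrays. With plate column as a block 946 genes were called. The scalings gave 514 higher and 235 lower (same median), 1238 and 129 (deposited values) and 515 and 81 (hybridisation controls), with medians over all genes of 0.072, 0.29 and 0.335. With only these 6 arrays in the fit 89 genes were called. The pooled error understates the spread of the WT LPS arrays, and with a separate spread for each group 438 genes were called, 221 higher and 217 lower, among them every gene named here. The count was 432 without KO replicate 2, 603 without KO replicate 3 and 545 without WT replicate 2, and 657 without WT LPS array 2 and 614 without KO LPS array 2. The calls for Cyp51, Havcr2, Clec10a, Timp1, Ifitm6, Saa2 and Arg1 ended in that smaller fit, with an adjusted p of 0.0793, 0.0632, 0.108, 0.0883, 0.197, 0.199 and 0.246, the highest over their alternatives. Ifitm6 and Saa2 also lost the call without WT replicate 2, and Arg1 without any of KO replicates 2 and 3 and WT replicates 2 and 3.

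By list, 12 of 19 pro-inflammatory cytokine genes were higher in KO cells after LPS and 0 lower (12 and 0 adjusted over the list alone; median 1.76, adjusted p = 2.63e-18, and 0.0106 with an estimated correlation). Examples were Il6 (3.00 ± 0.38), Il1a (1.94), Il12b (1.83) and Tnf (1.76). In the 3 plate columns its median was 1.13, 1.09 and 2.66. Of 19 cholesterol synthesis genes 13 were higher (15 over the list alone; median 1.36, adjusted p = 5.89e-16, and 0.105 with an estimated correlation; 1.85, 0.57 and 1.73 by column). Of 21 chemokine genes 6 were higher and 2 lower (9 and 2 over the list alone; median 0.78, adjusted p = 5.79e-05, and 0.105 with an estimated correlation; 0.23, 0.74 and 1.23 by column). They included Cxcl5 at 2.39, Cx3cl1 at 2.33, Ccl17 at 2.21 and Ccl8 at -2.21. Of 19 endoplasmic reticulum stress genes 7 were higher (9 over the list alone; median 0.50, adjusted p = 5.06e-08, and 0.105 with an estimated correlation; 0.51, 0.61 and 0.38 by column). Among its members were Herpud1 (0.99), Dnajb9 (0.85) and Hyou1 (0.77). Immediate early genes (3 higher and 1 lower of 20, 7 and 3 over the list alone, median 0.34, adjusted p = 0.00222, and 0.288 with an estimated correlation) included Egr2 at 2.03, Nr4a2 at 1.46 and Fos at -1.25. NRF2 targets (2 higher, 3 over the list alone, median 0.25, adjusted p = 0.000486, and 0.368 with an estimated correlation) included Slc7a11 at 1.54 and the quinone reductase gene Nqo1 at 0.93. MHC class II and co-stimulation (3 higher, 3 higher and 1 lower over the list alone, median 0.46, adjusted p = 0.00583, and 0.352 with an estimated correlation) included H2-Eb1 (1.20), Cd80 (1.01) and Icosl (0.95). It had column medians of -0.04, 0.63 and 0.75 and lost its call without WT replicate 3. NF-kB subunits and inhibitors (4 higher and 1 lower, 5 and 1 over the list alone, median 0.13, adjusted p = 0.0392, and 0.352 with an estimated correlation) included Rel at 0.95 and Nfkbiz at 0.91. This list lost the call without KO replicate 1 or 3 or WT replicate 1 or 2. For both lists the adjusted p ran up to 0.352 over the alternatives.

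Of the 5 lists called lower in KO cells after LPS none held with an estimated correlation. Of 7 monocyte markers 3 were lower and 0 higher (5 lower and 1 higher over the list alone; median -1.06, adjusted p = 0.00134, and 0.105 with an estimated correlation; -1.07, -0.69 and -1.33 by column). These were Hp, the coagulation factor gene F13a1 (-1.47) and Vcan (-1.31), and Ly6c1 was at -1.06 (adjusted p = 0.182). Of 23 macrophage identity genes 7 were lower and 1 higher (12 and 2 over the list alone; adjusted p = 0.000486, and 0.105 with an estimated correlation). Members included C1qb, Siglec1 (-1.98) and the Fc receptor gene Fcgr1 (-1.29), while C1qa was at -1.96 (adjusted p = 0.057). The median of this list was -0.32, but -0.01 with deposited values and 0.03 with equal hybridisation controls. Alternative activation markers (3 lower and 1 higher of 18, 6 and 3 over the list alone, median -0.54, adjusted p = 0.0139, and 0.105 with an estimated correlation) included Arg1, Clec10a and the mannose receptor gene Mrc1 (-1.11). Mgl2 was at -1.13 (adjusted p = 0.0948). Of 24 lysosomal genes 3 were lower, such as Ctsl (-0.55), and 5 over the list alone (adjusted p = 0.00207, and 0.265 with an estimated correlation). Their median of -0.15 became 0.14 with deposited values and 0.18 with equal hybridisation controls. Of 13 LXR targets 2 were lower (3 over the list alone; adjusted p = 0.00625, and 0.352 with an estimated correlation). Their median of -0.25 became 0.07 and 0.11 under those scalings, and the call ended without WT replicate 1. The interferon-stimulated genes had 1 higher member and a median of 0.01 (adjusted p = 0.896). Of the KLF3 targets measured, the galectin gene Lgals3 was at 0.13 (adjusted p = 0.533), C1qtnf12 at 0.06 (adjusted p = 0.848) and Stard4, a sterol transporter, at 0.95 (adjusted p = 0.0578), with 1 higher over the list alone. After LPS itself, C1qtnf12 fell by 1.09 in WT and by 1.21 in KO cells, Stard4 fell by 1.10 in WT cells and was at -0.47 in KO cells (adjusted p = 0.234), and Lgals3 was at -0.35 and -0.29. The Lgals3 change was past the threshold in both genotypes but lost in several alternatives, with an adjusted p of up to 0.689 in WT and 0.997 in KO cells.

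**Figure D3:**
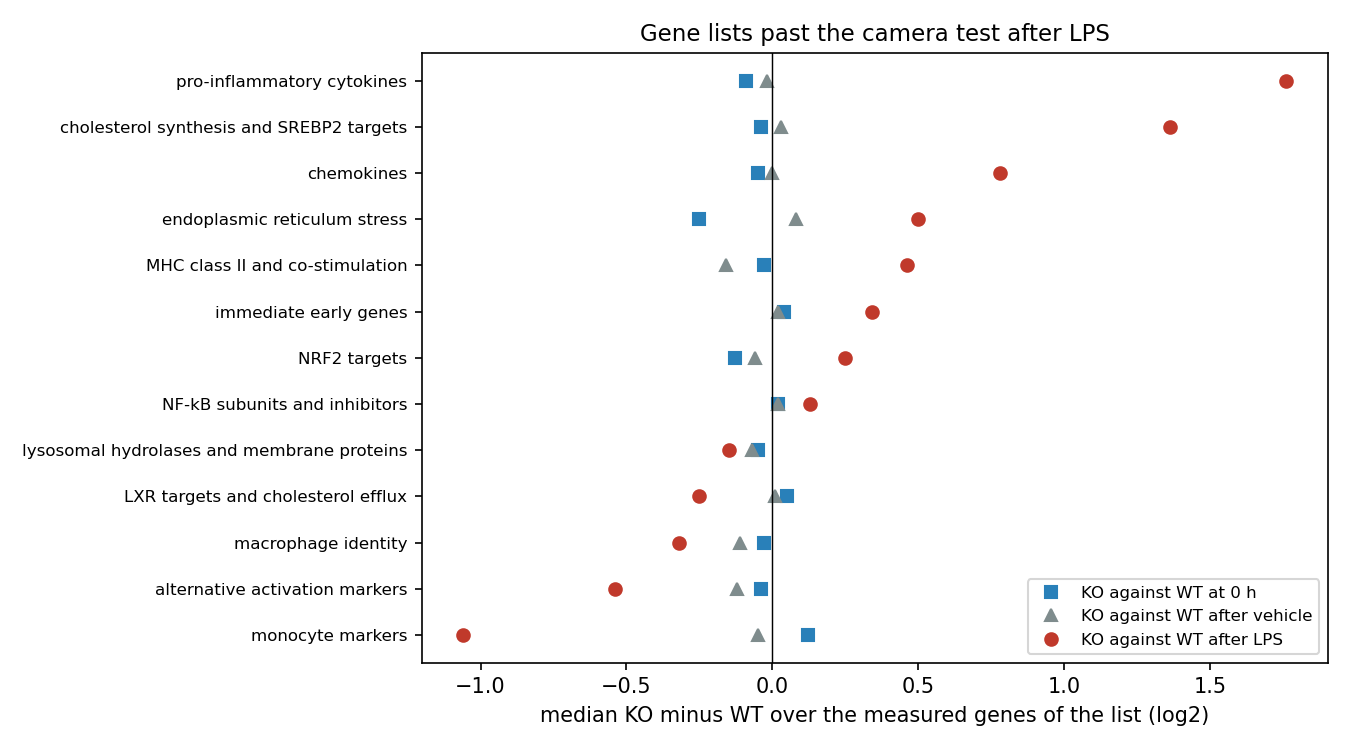
Median KO minus WT difference (log2) over the members of the 13 lists called after LPS, at 0 h (squares), after vehicle (triangles) and after LPS (circles). After LPS the medians are 1.76 for pro-inflammatory cytokines, 1.36 for cholesterol synthesis and -1.06 for monocyte markers; other scalings turn those of the macrophage identity (0.03), lysosomal (0.14 and 0.18) and LXR (0.07 and 0.11) lists upward.

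KO against WT at 0 h compares untreated cells. KO cells held more RNA of the integrin gene Itgb7 (2.79 ± 0.45 log2, n = 3 arrays each, 6.93-fold, adjusted p = 0.0174), the ficolin gene Fcna (2.48 ± 0.41, adjusted p = 0.0186), Rap1gap2, which switches off the small GTPase Rap (2.47 ± 0.34, adjusted p = 0.00588), and Pira1 (2.20 ± 0.35). Higher too were the adhesion receptor gene Adgre5 (1.84 ± 0.31), Tekt2 (1.83 ± 0.23, at least 1.83-fold), Ryr1 (1.73), Trim2 (1.71 ± 0.16, at least 1.13-fold, adjusted p = 0.000258), Klf9 (1.63 ± 0.29) and Cd109 (1.53). They held less of the integrin gene Itgb3 (-1.86 ± 0.27, at least 2.08-fold), Ccl5 (-1.56 ± 0.29, at least 2.47-fold), Cdhr3 (-0.95), Slc25a33 (-0.94) and the inhibitory Fc receptor gene Fcgr2b (-0.92 ± 0.13). In all, 24 genes passed, 19 higher and 5 lower, and 16 and 2 of them differed at least 2-fold. All 24 had 1 sign in the 3 plate columns, where Itgb7 was at 3.40, 2.63 and 2.35 and Itgb3 at -2.31, -1.05 and -2.24, and 21 genes were called with plate column as a block and 85 with a separate spread for each group. The split was 16 and 9 with arrays at the same median, 10 and 9 with deposited values and 15 and 12 with equal hybridisation controls. The count fell to 4, 1 and 12 without KO replicate 1, 2 or 3 and to 3 without WT replicate 1. Of the 15 genes named here, only Trim2 was called in every alternative that tested it (all but that without dim genes). The highest adjusted p over the alternatives was 0.188 for Itgb7, 0.0956 for Rap1gap2 and 0.171 for Itgb3.

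No member of the interferon-stimulated list passed at 0 h over all genes, but 18 of 35 were lower in KO cells when adjusted over the list alone, with a median of -0.55 (adjusted p = 4.42e-23, and 0.292 with an estimated correlation). The largest values were -1.86 for Ifit2 (adjusted p = 0.178), -1.68 for Ifit1 (adjusted p = 0.0639), -1.61 for Ifit3 and -1.47 for Usp18, and the median was -0.77, -0.33 and -0.56 in the 3 plate columns. Endoplasmic reticulum stress genes (0 of 19 past the threshold, 5 lower over the list alone) had a median of -0.25 (adjusted p = 5.44e-11, and 0.291 with an estimated correlation). Chac1 was at -1.77 and Asns at -1.48, and the column medians were -0.40, -0.13 and -0.49. MHC class I and antigen processing (0 past either threshold) had a median of -0.15 (adjusted p = 0.0119, and 0.752 with an estimated correlation), and its call ended without KO replicate 2 or 3. The neutrophil protease gene Mmp8 was higher in KO cells (1.31, adjusted p = 0.00588). C1qtnf12 was at 0.46 (adjusted p = 0.256) with 1 KLF3 target higher over the list alone, and Lgals3 and Stard4 were at 0 and 0.05 (adjusted p = 1 and 0.999).

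After 8 h of vehicle no gene passed between genotypes by limma. At an unadjusted p under 0.05 there were 777 genes, and the smallest adjusted p was 0.053. The genes with the smallest p were L1cam, a cell adhesion molecule (2.11 ± 0.31, adjusted p = 0.053), Klf3 itself (-1.92, adjusted p = 0.053), Rap1gap2 (1.92 ± 0.34, adjusted p = 0.192) and Itgb7 (2.42 ± 0.45, adjusted p = 0.232), n = 3 arrays each. L1cam was not past the threshold at 0 h (adjusted p = 0.0775) and was higher in KO cells after LPS (1.54, adjusted p = 0.00623), as was Rap1gap2 (2.35, adjusted p = 0.000498), and Itgb7 was at 1.03 after LPS (adjusted p = 0.212). The median over all genes was 0.006, and -0.105, -0.155 and -0.126 with equal medians, deposited values and equal hybridisation controls. Other settings called 2 genes with a dim filter, averaged probe sets, trend and robust settings or plate column as a block, 6 when every probe set was tested or hybridisation controls were equalised, 7 with a separate spread for each group, and 4 and 1 without WT replicates 2 and 3. The proliferation list had a median of 0.41 (0 of 34 past the threshold, adjusted p = 5.43e-09, and 0.921 with an estimated correlation). Its column medians were 0.03, 0.21 and 1, and the call ended without KO replicate 3, whose vehicle array had the widest spread of its group. Alternative activation markers (0 past the threshold, 1 lower over the list alone) had a median of -0.12, but 0 with values raised to the nonspecific level (adjusted p = 0.011, and 0.127 with an estimated correlation). Macrophage identity genes had one of -0.11 (adjusted p = 0.0163, and 0.684 with an estimated correlation). The former call ended without KO replicate 2 or WT replicate 1 and the latter without KO replicate 3 or WT replicate 1.

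Vehicle against 0 h in WT cells follows 8 h in regular medium without the conditioned medium. Id3, an inhibitor of basic helix-loop-helix factors, rose by 6.42 ± 0.31 (log2 ± SE, n = 3 arrays each) and by 6.66 in KO cells. In WT cells rises followed in the arginine transporter gene Slc7a2 (4.31 ± 0.52), Fabp7 (3.80), Acod1 (3.68), the caveolin gene Cav1 (3.54), Arg2 (3.29, at least 2.62-fold), the repressor gene Prdm1 (3.09), Enc1 (3.09), the integrin gene Itgal (3.07) and Apoc2 (2.97). The largest falls were in the monocyte attractants Ccl7 (-5.79 ± 0.63) and Ccl2 (-4.28), in the cyclin genes Ccnd1 (-5.04) and Ccne2 (-4.02, at least 7.2-fold lower), and in Tnfsf9 (-3.80). Other falls were in Stat4 (-3.55), the growth factor-induced genes Etv5 (-3.37) and Ets2 (-3.35), Ch25h (-3.32) and the survival gene Bcl2 (-3.23). In KO cells Slc7a2 (4.75), Itgal (3.86), Acod1 (3.79), Cav1 (3.37), Ppp1r12b (3.21, at least 6.83-fold), Arg2 (3.17, at least 1.98-fold) and Skil (2.97) rose. In the same cells Ccl7 (-6.24), Ccnd1 (-5.17), Ccl2 (-4.18), Stat4 (-4.02, at least 11.2-fold lower), Ednrb (-3.91), Etv5 (-3.89), Dok2 (-3.71), Ccr1 (-3.71), Ccnd2 (-3.64) and Clec10a (-3.53) fell. In WT cells 2424 genes passed, 1226 higher and 1198 lower, with 221 and 458 at least 2-fold. In KO cells 2150 passed, 1159 higher and 991 lower, with 205 and 349 at least 2-fold. Of these, 823 rose in both genotypes (83.1 expected for independent lists) and 707 fell in both (69.4 expected), with r = 0.807 across genes, which are not independent replicates. The directions followed the scaling, with 464 higher and 1420 lower in WT and 337 and 2048 in KO cells at equal medians, 222 and 1465 and 199 and 1559 with deposited values, and 171 and 601 and 128 and 623 with equal hybridisation controls. The median of all genes was then -0.11, -0.203 and -0.098 in WT and -0.216, -0.256 and -0.22 in KO cells. The WT count was 1489 and 1237 without WT replicates 2 and 3, and the KO count was 756 and 951 without KO replicates 1 and 2.

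No list called between vehicle and 0 h held with an estimated correlation (adjusted p from 0.0936 to 0.649). Of 34 proliferation genes 22 fell in WT cells (28 adjusted over the list alone; median -0.93, adjusted p = 4.94e-17). In KO cells 13 fell (17 over the list alone; median -0.69, adjusted p = 4.82e-10). They included the replication genes Uhrf1 at -3.01 and -1.80 and Mcm6 at -2.63 and -1.99. Of 19 cholesterol synthesis genes 7 fell in each genotype (medians -0.77 and -0.64, adjusted p = 2.6e-06 and 2.66e-06). Over the list alone 14 fell and 1 rose in WT and 12 fell in KO cells. Of 19 endoplasmic reticulum stress genes 12 fell and 1 rose in WT cells (median -0.82, adjusted p = 3.12e-07). Examples were Chac1 at -2.73 and Trib3 at -2.13, and in KO cells these were at -0.75 each (adjusted p = 0.4 and 0.416; list adjusted p = 0.068). Of 35 interferon-stimulated genes 10 fell in WT cells (17 over the list alone; median -0.59, adjusted p = 8.87e-07). In KO cells 3 rose and 3 fell (median -0.14, adjusted p = 0.706). NF-kB subunits and inhibitors rose, 9 of 19 with 1 lower in WT (11 and 1 over the list alone; median 0.48, adjusted p = 3.86e-05). In KO cells 10 rose (10 higher and 2 lower over the list alone; median 0.45, adjusted p = 1.7e-05). They included Nfkbia (1.21 and 1.09) and Relb (1.20 and 1.55). Of 10 nitric oxide, itaconate and superoxide enzymes 6 rose and 1 fell in each genotype (medians 0.68 and 0.64, adjusted p = 0.00012 and 0.000142).

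Over the vehicle period lysosomal genes (7 of 24 higher in each genotype, 10 and 9 over the list alone, adjusted p = 0.000483 and 4e-04) included Scarb2 (0.92 and 0.88) and Gla (0.86 and 0.67). The medians were 0.21 and 0.18, and that of KO cells became -0.12 with deposited values, -0.08 with equal medians and -0.09 with equal hybridisation controls. Chemokines (1 higher and 5 lower in WT, 2 and 7 in KO cells, and 1 and 6 and 2 and 8 over the list alone, medians -0.24 and -0.29, adjusted p = 0.00982 and 0.0163) included Ccl12 (-3.23 and -2.51). With values raised to the nonspecific level these medians were -0.23 and -0.18, as in lists at background, so they show no fall. The KO call ended without KO replicate 3. Immediate early genes (2 higher and 7 lower in WT, 1 and 7 in KO cells, where 2 and 8 passed over the list alone, medians -0.24 and -0.29, adjusted p = 0.0185 and 0.0106) included Myc (-2.93 and -3.45) and Egr1 (-2.87 and -2.25). The WT call ended without WT replicate 2. MHC class II and co-stimulation (4 and 3 of 14 lower, 5 and 3 over the list alone, medians -0.25 and -0.36, adjusted p = 0.0457 and 0.00711) included Cd40 (-1.44 and -1.70). The call in WT ended without KO replicate 2 or 3 or WT replicate 2. Glycolysis and HIF1 targets in WT cells (1 higher and 5 lower, median -0.27, adjusted p = 0.0343) included Pfkp (-1.46), and the call ended without WT replicate 1 or 3. NRF2 targets (4 and 3 of 18 higher, 4 and 5 over the list alone, adjusted p = 0.00494 and 0.00258) included Gclm, which limits glutathione synthesis (1.77 and 1.98). Their medians were 0.20 and 0.31, but -0.04 and -0.01 with deposited values, and the calls ended without WT replicate 3 and KO replicate 3.

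No gene differed between genotypes in the response to vehicle by limma. At an unadjusted p under 0.05 there were 629 genes, between 150 and 994 in the other settings, all of which called 0 after adjustment, and the smallest adjusted p was 0.999. Among the smallest p were Glt28d2 (0.87 ± 0.19), Pald1 (1.43 ± 0.32) and the immediate early gene Fosb (1.36 ± 0.31), each with adjusted p = 0.999. By list, interferon-stimulated genes had a median of 0.46 (0 past the threshold, 5 higher over the list alone, adjusted p = 9.83e-11, and 0.63 with an estimated correlation). Endoplasmic reticulum stress genes had a median of 0.38 (adjusted p = 2.17e-08, and 0.25 with an estimated correlation) and proliferation genes one of 0.35 (adjusted p = 7.67e-05, and 0.818 with an estimated correlation). Glycolysis and HIF1 targets were at 0.16 (adjusted p = 0.00907, and 0.795 with an estimated correlation) and neutrophil markers at -0.21 (adjusted p = 0.0379, and 0.25 with an estimated correlation). The neutrophil median was 0.05 with values raised to the nonspecific level, so its direction is not settled. The proliferation call ended without KO replicate 3 or WT replicate 3, the glycolysis call without KO replicate 3 or WT replicate 1, and the neutrophil call without KO replicate 1 or 2 or WT replicate 1 or 2 (adjusted p up to 0.335 over the alternatives).

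Averaged over the 3 conditions, KO cells held more Rap1gap2 (2.25 ± 0.18 log2, n = 3 averages of same-numbered arrays per genotype, adjusted p = 0.00387), Itgb7 (2.08, adjusted p = 0.0284), Csf2 (2.06, adjusted p = 0.000759), and Fcna (1.85). Also higher were L1cam (1.72), Havcr2 (1.68), Pira1 (1.58), Cd109 (1.40), Lif (1.39) and Nr4a3 (1.38). They held less Klf3 (-1.79, adjusted p = 0.00887), C1qb (-1.71), Cacna1d (-1.31), the granulocyte growth factor receptor gene Csf3r (-1.11), Siglec1 (-1.04), Timp1 (-0.99), Gab3 (-0.98, adjusted p = 0.00656), Hp (-0.95), Sfxn5 (-0.94) and the sorting receptor gene Sorl1 (-0.94). Some averages rest on LPS alone. KO minus WT at 0 h, after vehicle and after LPS was 0.10, -0.08 and 6.18 for Csf2, 0.16, 0.12 and 3.88 for Lif, 0.11, 0.20 and 3.84 for Nr4a3 and 0.16, -0.11 and -2.90 for Hp, while it was 2.47, 1.92 and 2.35 for Rap1gap2. In all, 63 genes passed, 42 higher and 21 lower, and the split was 83 and 64 with equal medians, 63 and 34 with deposited values and 74 and 33 with equal hybridisation controls. The count was 37, 13 and 17 without KO replicate 1, 2 or 3 and 16 and 33 without WT replicate 1 or 2. Of the genes named here Rap1gap2, Csf2, Lif and Gab3 were called in every alternative that tested them (Lif was not tested without dim genes), and Klf3 lost its call without WT replicate 1 (adjusted p = 0.0527, the highest over its alternatives).

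In the average, pro-inflammatory cytokines (5 higher of 19, 12 over the list alone, median 0.48) and cholesterol synthesis genes (0 past the threshold, 13 higher over the list alone, median 0.44) were called upward. Each had adjusted p = 2.33e-11, and adjusted p = 0.44 and 0.51 with an estimated correlation. Both rest on LPS, with medians of -0.09 and -0.04 at 0 h, -0.02 and 0.03 after vehicle and 1.76 and 1.36 after LPS. Proliferation genes had a median of 0.20 (0 past either threshold, adjusted p = 0.000732, and 0.712 with an estimated correlation) and immediate early genes one of 0.10 (1 higher, 2 over the list alone, adjusted p = 0.03, and 0.711 with an estimated correlation). Downward calls were macrophage identity (2 lower of 23, 6 lower and 2 higher over the list alone, median -0.13, adjusted p = 0.000812, and 0.54 with an estimated correlation) and lysosomal genes (0 past either threshold, median -0.08, adjusted p = 0.00193, and 0.603 with an estimated correlation). So were alternative activation markers (0 past the threshold, 1 higher and 3 lower over the list alone, median -0.17, adjusted p = 0.00287, and 0.51 with an estimated correlation). The interferon-stimulated genes were called downward (0 past either threshold, median -0.20, adjusted p = 1.06e-06, and 0.711 with an estimated correlation). Other downward calls were LXR targets (0 past the threshold, 1 lower over the list alone, median -0.24, adjusted p = 0.03, and 0.711 with an estimated correlation) and osteoclast markers (0 of 10 past the threshold, 1 higher and 2 lower over the list alone, median -0.22, adjusted p = 0.0386, and 0.603 with an estimated correlation). Without single replicates the calls for proliferation (KO 3), immediate early genes (KO 2, WT 1 or WT 2), interferon-stimulated genes (WT 1), LXR targets and osteoclast markers (KO 3, WT 1 or WT 2) ended.

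Several lists were never called. In the KLF and SP family (21 measured) 8 members fell and 1 rose with LPS in WT cells, such as Klf4 (-2.57), Klf2 (-1.65) and Klf9 (-1.36). The median was -0.20 (adjusted p = 0.104). Raising values to the nonspecific level gave 0.20, and 0.26 for lists at background, so it shows no rise. After LPS 2 were lower in KO than in WT cells (3 lower and 1 higher over the list alone), Klf3 and Klf10 (-1.29), with a median of -0.08 that became 0.18 with deposited values (adjusted p = 0.558). With LPS in WT cells, KLF3 cofactors had a median of -0.05 (2 of 8 higher, 2 lower, adjusted p = 0.922), with Fhl3 at 1.39, and galectins one of 0.08 (2 of 8 higher, 1 lower, adjusted p = 0.4), with Lgals9 at 1.95. Between genotypes after LPS these medians were -0.11 (adjusted p = 0.867) and 0.05 (adjusted p = 0.728).

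For markers of other cell types the median KO minus WT difference after LPS is given. Apart from the osteoclast list these medians rest mostly on background. Of the 109 markers in the 10 other lists 25 lay above the nonspecific level in all 3 arrays of a group, and with values raised to that level the median of each of the 10 was -0.07. Dendritic cell markers (10 measured) had a median of -0.12 (adjusted p = 0.897), T and NK cell markers (15) 0.06 (adjusted p = 0.701), and B cell and plasma cell markers (11) 0.16 (adjusted p = 0.124). Eosinophil markers (6) were at -0.17 (adjusted p = 0.826), stromal and fibroblast markers (16) -0.15 (adjusted p = 0.701) and neutrophil markers (13) 0.03 (adjusted p = 0.701). Erythroid and megakaryocyte markers (12) had a median of 0.06 (adjusted p = 0.558) with 1 member higher, Ppbp (1.03). Mast cell and basophil markers (11) were at -0.02 (adjusted p = 0.701), and Hdc, which makes histamine, was higher. Endothelial and adipocyte markers (9) were at -0.06 (adjusted p = 0.806) with Vwf (1.62) higher. Stem and progenitor markers (8) were at 0.03 (adjusted p = 0.57) with Gfi1 (1.03) higher. Osteoclast markers (10) had 2 lower members, Mmp9 (-2.17) and Calcr (-0.97), with 2 lower and 1 higher over the list alone, and a median of -0.34, -0.16 with that floor (adjusted p = 0.229). Among the neutrophil markers S100a8 (-1.28) was lower.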

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

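The tests of array brightness, of single arrays left out, of a separate spread for each group and of the genes flanking Klf3, the values raised to the nonspecific level, and the reverse check on the genes with the smallest p after vehicle were chosen after the results they concern had been seen. The LPS response of 191 genes differed between genotypes by the interaction test, and the 10 largest differences in each direction stood out too. These differences in response (KO minus WT, log2) were 6.26 (Csf2), 3.82 (Il23a), 3.76 (Lif), 3.72 (Inhba), 3.68 (Il12a), 3.65 (Nr4a3), 3.62 (Adamts4), 3.20 (Lad1), 3.16 (Cyp51) and 3.13 (Egr2). In the other direction they were -4.56 (Saa1), -2.79 (Hp), -2.78 (Gins1), -2.73 (Cacna1d), -2.70 (Ly6i), -2.59 (Timp1), -2.58 (Zc3h12d), -2.38 (Zfp618), -2.33 (Zdhhc14) and -2.33 (Adssl1). Some rest on groups under the nonspecific level and were smaller with values raised to it, as given above.

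For this pattern of 191 genes, array brightness and normalization were set against the genotype, since WT LPS arrays had the lowest mean upper quartile. Of the 89 higher genes 67 were called under all 4 scalings, of the 102 lower genes 9. The other scalings raised the all-gene median to 0.171, 0.44 and 0.456, favouring such calls, so brightness stays open for the 67. The lower genes kept their sign, with a median of -1.07 (equal medians), -0.80 (deposited values) and -0.79 (equal hybridisation controls) against -1.29. The median all-gene standard error rose from 0.26 to 0.29, 0.33 and 0.43, so calls were lost with a smaller difference and larger error. For lower genes beyond the 9, genotype and normalization cannot be told apart, since genes picked for a low value keep part of it. WT LPS array 1, which had the widest spread, was the next candidate, but without it the median absolute difference of the 191 genes was 1.01 times its value with it, 0% changed sign, 188 of the 191 were among the 499 genes then called, and this argues against that array as the source. T, NK, mast or dendritic cells more abundant in KO cultures could not be excluded: the largest marker median was 0.98, from Hdc alone among mast cell markers, while T and NK cell markers had medians of 0.06 after vehicle and -0.31 after LPS and dendritic cell markers -0.12 and 0.30, so a difference in cell composition and an effect of the genotype within macrophages both stay open.

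A second pattern was the 24 genes called between genotypes at 0 h against none after vehicle, where 777 genes had an unadjusted p under 0.05 (85 and 7 with a separate spread for each group). Without KO vehicle array 3, which had the widest spread of its group, 0 genes were called by limma (844 at an unadjusted p under 0.05) and the median difference of the 24 genes was 0.66, against 0.58 with it. Without 1 KO array at 0 h, 7 to 10 genes were still called and that median was 1.48 to 1.60, so fewer arrays alone do not bring the count to 0, and this argues against that array as the cause. Genotype differences smaller after 8 h of vehicle were tested on the 24 genes, whose median difference in the direction of 0 h went from 1.55 to 0.58, a ratio of 0.374, with 23 of 24 keeping their sign and 14 of 24 past the test of the difference over these genes alone. Genes picked for a large value at one time are likely to be smaller at another, and the reverse check gave a ratio of 0.72 (0.92 after vehicle and 0.67 at 0 h, for the 24 genes with the smallest p after vehicle), so a true fall with time and this selection cannot be told apart with 3 arrays per group.

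Genes within 10 Mb of Klf3, where sequence of another strain could flank a targeted gene, gave 0 calls among 66 in the average over conditions, with 0.243 expected, too few to decide. After LPS 4 of 66 were called, namely Apbb2, Dcun1d4, Shisa3 and Tec (Fisher's exact test, two-sided, p = 1 against the other genes).

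Splits of the same arrays or same-numbered sets were too few, at 10 for each comparison, for a share under 0.05, so only the counts are given. For LPS in WT cells the real split called 5522 genes and the highest other 0, and for LPS in KO cells 5894 and 0, with 1 of the 10 splits, the real one, reaching the count. The interaction gave 191 against 1, KO against WT at 0 h 24 against 0, after LPS 1019 against 22, and over the 3 conditions 63 against 0. Vehicle against 0 h gave 2424 against 0 in WT and 2150 against 0 in KO cells. KO against WT after vehicle called 0 genes in the real split and up to 1 in another, and the difference in vehicle response 0 in all, so that 10 of 10 splits reached the count (777 and 629 genes at an unadjusted p under 0.05 in the real split, by limma).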

How the results depend on the processing

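Deposited values, equal hybridisation controls, a separate spread for each group and the omission of single arrays were chosen after seeing the data, and the other settings were planned. Of the gene counts under alternatives, 134 stayed within 1.5 times the reported count and 59 did not. Of the values for named genes 3407 kept direction and call, 234 lost the call, 39 gained one and 1 reversed. For the list tests the numbers were 3334, 152, 110 and 4. Where no cause is named below, the cause was not tested.

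Testing every probe set, which adds features, called 11337 (LPS in WT), 12403 (LPS in KO), 6 (KO against WT after vehicle), 1720 (after LPS), 5173 and 4875 (vehicle against 0 h in WT and KO) and 101 (average over conditions). Equal hybridisation controls gave 3442 for LPS in KO, 122 for the interaction, 6 after vehicle, 596 after LPS, 772 and 751 over time and 107 for the average. Deposited values gave 294 for the interaction and 97 for the average, and equal medians 147 for the average. With only the groups compared in the fit 80 genes were called for the interaction and 89 after LPS. With a separate spread for each group 85 genes were called at 0 h, 7 after vehicle, 438 after LPS and 3707 over time in WT. The median SD of a gene was 0.243 in the WT LPS group and 0.136 to 0.179 in the others. After vehicle 2 genes were called with a dim filter, averaged probe sets, trend and robust settings, the plate column block or the replicate number within genotype as a random block. The average gave 95, 184, 28 and 231 with averaged probe sets, trend and robust settings, the plate column block and the random block.

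Leaving out each replicate number of a genotype, which lowers the number of samples, gave 4280 to 5350 calls for LPS in WT, 4461 to 6118 for LPS in KO, 70 to 222 for the interaction, 1 to 30 at 0 h, 0 to 4 after vehicle, 432 to 1146 after LPS, 1237 to 2335 and 756 to 2412 over time in WT and KO, 0 to 0 for the difference in vehicle response (629 genes at an unadjusted p under 0.05 by limma with all arrays, 150 to 994 in the other settings) and 13 to 53 for the average. Without single LPS arrays the interaction gave 499, 145 and 373 (WT arrays 1, 2 and 3) and 243, 134 and 123 (KO arrays), and KO against WT after LPS ran from 614 to 1500. Without KO vehicle array 3 the interaction called 223.

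Pairing by replicate number stays open. Correlations of deviations from the group mean between arrays sharing number and genotype ran from -0.046 to 0.144, with 2 of 18 over 0.1. With the number within genotype as a replicate block, 5433 and 5844 genes were called for LPS in WT and KO, 154 for the interaction, 2354 and 2077 over time and 0 for the difference in vehicle response. With the number shared by WT and KO as a block 32 genes were called at 0 h, 0 after vehicle, 994 after LPS and 48 for the average. Leaving out genes near Klf3 gave 24, 0, 1014 and 62 for the same comparisons.

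The tested direction reversed in 5 values. With equal medians the Lgals3 response to LPS in KO cells was 0 (log2, adjusted p = 0.997). The respiratory chain list turned upward for LPS in KO cells with adjusted p = 0.582 (equal medians), 0.74 (deposited values) and 0.705 (equal hybridisation controls). The proliferation list turned upward for the interaction without KO replicate 3 (adjusted p = 0.741), with 0.000309 without KO replicate 2. Camera tests a list against all other genes, so a list median can change sign while its tested direction stays. Of 97 list calls, 10 had a median that changed sign under 1 or more of the 3 other scalings, and the report gives these medians. Genes under the nonspecific control level have no measurable fold.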

Other observations

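The list of genes known to respond to GM-CSF or its mediator STAT5 was chosen, and its test set, before the values of these genes were seen. The tests of this list after LPS alone and after vehicle alone were chosen afterwards. Csf2, under the nonspecific control level in WT cells, rose in KO cells after LPS, together with Cish, a STAT5-induced inhibitor (2.80 ± 0.24 for the interaction, n = 3 arrays per group), and with Ccl22 and Ccl17, chemokines known to follow GM-CSF. A hypothesis is that secreted GM-CSF acts back on KO cells, so that other genes responding to it would have larger LPS responses in KO cells. Over 10 such genes the mean difference in response was 0.51 (log2) and the median 0.57, with 6 of 10 above 0 (camera p = 0.016 in limma, and p = 0.0311 with an estimated correlation). None passed the threshold alone, the largest being Socs1 (1.51, adjusted p = 0.341), Ccnd2 (1.04, adjusted p = 0.568) and Pim1 (0.99, adjusted p = 0.156), while Irf4 was at -0.29 and Il2ra at -0.12. Part of this came from lower levels in KO cells after vehicle, where the mean KO minus WT difference of the 10 genes was -0.32 (camera in limma at the preset correlation, p = 0.0176), with Ccnd2 at -0.99 and Mgl2 at -1.53. After LPS the mean was 0.19 (p = 0.211 at the same correlation), with Ccnd2 at 0.05 and Mgl2 at -1.13. A response to secreted GM-CSF may be present, but these values do not decide it, and the genes may also respond to LPS directly.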
